A study of Homo sapiens with 6 samples.

How the data were processed

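The data are small RNA sequencing libraries of exosomes from EKVX cells, an established human non-small cell lung cancer line. Per the labels, 3 libraries came from cells with a scramble control and 3 from cells in which syndecan-1, a cell-surface heparan sulfate proteoglycan, was knocked down. All 3 knockdown libraries carry the same tag in their titles, and their columns of values are headed KO. With a shared tag, effects particular to 1 construct or line cannot be told apart from loss of syndecan-1. Per the labels' protocols, cells at passage 6 to 8 were kept for 48 h in medium with 10% exosome-depleted fetal bovine serum. Exosomes were then precipitated from that medium with a polymer reagent, and microRNA was purified on columns and made into Illumina libraries. The labels number the replicates 1 to 3 in each group but do not say that they came from separate cultures, so every p-value measures the spread between these samples, which can be technical.

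The authors deposited a single table of read counts scaled to the library total (CPM) for 2588 mature human miRNAs. Each of the 6 columns summed to 1000000 over the miRNA rows, so a value is a share of the reads assigned to miRNAs and not an amount per cell or per exosome. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.3 and the genome build was GRCh38. The counting tool, adapter trimming, length limits, the treatment of reads with several matches, strand handling and the miRBase release are not given in the sources used here. The table ended in 2 blank rows, which were left out and hold no reads. In every library 100% of the deposited CPM values were whole multiples of the value of 1 read, within a tolerance of 0.001 reads. The recovered totals were 2360292, 2742909 and 2285283 reads in scramble replicates 1 to 3 and 2340725, 1930416 and 3613206 reads in knockdown replicates 1 to 3. One read was worth between 0.277 and 0.518 CPM, and the limit that a count of 0 allows (3 reads) lay between 0.830 and 1.55 CPM. Such limits cover counting error only, because the reads carry no molecular identifiers that are used here.

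Values were analysed as log2(CPM + 1), for the rows with a CPM of at least 10 in at least 3 of the 6 libraries. This left 428 rows, which hold 99.8% of the CPM. A fold change on this scale understates the change of low rows. Knockdown was compared with scramble in limma 3.58.1 (R 4.3.3) with eBayes and a trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over the 428 rows and a threshold of 0.05 on the adjusted p. No replicate block was used. The libraries were not rescaled beyond the authors' own CPM scaling. All folds given as ratios are ratios of the group means of CPM.

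Before the data were examined, 18 miRNA lists were fixed: the let-7, miR-15/16, miR-29, miR-30, miR-34/449, miR-181 and miR-99/100/125/10 families, the miR-17-92 cluster with its paralogs, the miR-23-27-24 clusters, the miR-200 family with miR-205, the 14q32 imprinted cluster, the 19q13 primate cluster, the miR-371-373 cluster, oncogenic and suppressor miRNAs of lung cancer, markers of blood cells and endothelium, markers of liver, muscle and neural tissue, and entries that overlap other noncoding RNA. Both arms and all copies of a member count as its rows. Lists with at least 3 tested rows were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks whether the members of a list move one way on balance. In fry the members are set against no change, and in camera against the other tested miRNAs. A shift shared by all rows can therefore make a list pass in fry, which was run at the deposited scaling only. Counts "adjusted over the list alone" use the Benjamini-Hochberg adjustment within that list.

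The miRNAs named in the text followed a rule fixed at the same time. It took the 12 rows with the largest absolute change in each direction among those past the test whose groups did not overlap, the 8 most abundant rows, and for each list with at least 3 tested rows the members past the test, at most 4 by size of change. Other miRNAs named in the text were chosen after their values were seen, as parts of a list count or of a pattern.

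Other settings were a pseudocount of 0.1 or 10, a CPM filter of 1 or 100 or none, TMM factors, quantile normalization, rescaling without the 10 most abundant rows, limma with no trend, a replicate block, the sum of the copies of a miRNA, and leaving out each library in turn. Count models were run on the recovered reads, namely edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. After the data were seen, a further setting kept 1 of each pair of rows with the same reads in all 6 libraries. The share of CPM in the 10 most abundant rows, the number of miRNAs detected and the share of CPM in entries overlapping other noncoding RNA were compared by an exact permutation test of the group means, for which 3 against 3 libraries cannot give a p below 0.1.

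The test was checked on simulated counts drawn from the means and depths of these libraries, with known changes in part of 424 simulated rows. The limma test recovered 18 of 31 rows changed 1.5-fold, 37 of 42 changed 2-fold and all 30 changed 4-fold. It also called 35 of 321 unchanged rows, against 5 after TMM scaling, 4 with edgeR and 6 with DESeq2, because CPM values of unchanged rows shift when the make-up of the library changes. This was a single draw, with the known changes drawn about evenly as increases and decreases and most rows unchanged. In the data 264 of 428 rows were called, so these rates, and the lower ones after TMM scaling, need not carry over. Replicates of a group were compared by a chi-square test of their reads. No pair agreed within counting noise (chi-square per degree of freedom between 9.42 and 49.7), so none looked like a second deposit of the same library. This test cannot tell separate cultures from technical repeats.

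Precursor positions are from GENCODE 29, an annotation of GRCh38, the build that the processing notes name. It may not be the annotation the authors used. Of the 2588 rows, 2542 had a precursor in it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and plots. Target messages of the miRNAs, syndecan-1 itself and miRNA sequence motifs were not analysed here.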

Results

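The data describe which miRNAs were carried by exosomes, small vesicles released into the culture medium, from human EKVX lung cancer cells with a scramble control (3 libraries) or with syndecan-1 knocked down (3 libraries). The series asks how syndecan-1 bears on the miRNAs packaged in exosomes. The libraries held between 1930416 and 3613206 reads assigned to mature miRNAs. Syndecan-1 itself is a messenger RNA and a protein, so these miRNA values hold no check of the knockdown.

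Exosomes of the knockdown cells carried far more miR-675, which is processed from an exon of the imprinted noncoding RNA H19, than exosomes of scramble cells. The mean CPM of miR-675-5p was 14.8 ± 3.82 in scramble and 565 ± 89.2 in knockdown (SD, n = 3 per group), a ratio of 38.2 and a log2 fold change of 5.18 (SE 0.19). Epithelial miRNAs of the miR-200 family, which restrain the ZEB repressors of E-cadherin, also rose, led by miR-200c-3p from 3899 ± 803 to 17554 ± 1288 CPM (log2 fold change 2.19, SE 0.13). Members of the imprinted cluster at 14q32 rose with them, for example miR-409-3p from 33.7 ± 10.7 to 186 ± 39.6 CPM (log2 fold change 2.45, SE 0.22). In the other direction, miR-30b-5p fell from 4541 ± 322 to 1650 ± 148 CPM (log2 fold change -1.46, SE 0.10) and miR-145-5p, a tumour suppressor miRNA, fell from 733 ± 106 to 292 ± 9.33 CPM (log2 fold change -1.32, SE 0.12).

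Of the 428 miRNAs tested, 171 were higher and 93 were lower in knockdown exosomes at an adjusted p under 0.05 in limma, and 164 did not pass. Of the higher calls, 19 had every scramble library under the CPM filter of 10, and 4 of the lower calls had every knockdown library under it, so such rows could enter the test in 1 direction only. At least 2-fold changes were found for 71 of the higher and 21 of the lower miRNAs. The 2 groups did not overlap for 285 of the 428 miRNAs (66.6%, where chance gives 10%). With TMM scaling, which lowers the median log2 fold change of all tested miRNAs from 0.18 to -0.10, a shift of 0.283, 111 miRNAs were higher and 154 lower, so the split between higher and lower depends on the scaling. None of the 264 calls passed the test in the opposite direction under any setting tried, and 204 of them kept their direction and passed after TMM scaling.

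**Figure D1:**
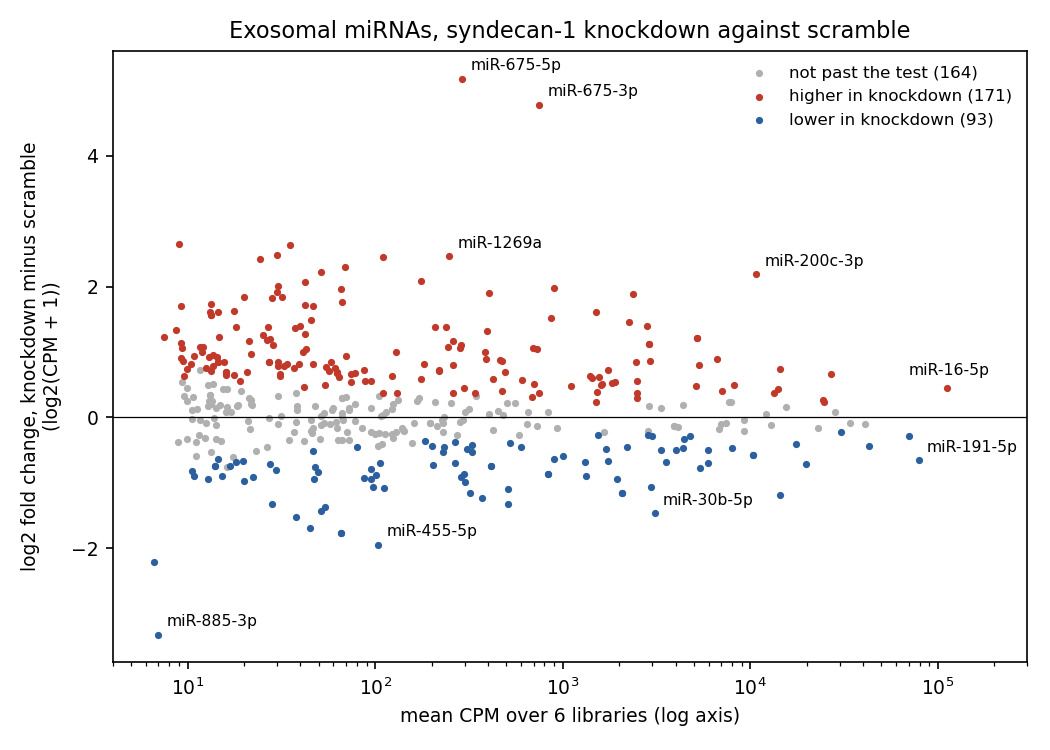
Each point is 1 of the 428 tested miRNAs, with its mean CPM over 6 libraries on a log axis and its log2 fold change (knockdown minus scramble, log2(CPM + 1)) on the vertical axis. Red points (171) were higher and blue points (93) lower in knockdown at an adjusted p under 0.05, grey points (164) did not pass; miR-675-5p and miR-675-3p lie highest at 5.18 and 4.78, and after TMM scaling the counts are 111 higher and 154 lower.

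After the 2 arms of miR-675 (miR-675-3p rose from 53.5 ± 18.6 to 1451 ± 188 CPM), most of the miRNAs with the largest increases were low to moderate in abundance, with the exception of miR-200c-3p above. miR-373-3p rose from 1.76 ± 0.0643 to 16.3 ± 0.859 CPM, miR-184 from 8.39 ± 0.510 to 51.6 ± 3.06 CPM and miR-1269a from 76.1 ± 13.8 to 421 ± 57.6 CPM. Further increases were those of miR-1226-3p (log2 fold change 2.43, SE 0.24) and miR-934 (2.08, SE 0.19), and, from 14q32, miR-654-3p (2.64, SE 0.26), miR-323a-3p (2.31, SE 0.23) and miR-134-5p (2.23, SE 0.22). The adjusted p of these increases lay between 2.6e-09 for miR-675-5p and 5.4e-06 for miR-323a-3p. The miR-675 precursor lies on chromosome 11 at 1996759 to 1996831 (GRCh38, minus strand), in an exon of H19. The miR-184 precursor (chromosome 15, 79209788 to 79209871, plus strand) overlaps no other gene on its strand, and the miR-1269a precursor (chromosome 4, 66276824 to 66276928, plus strand) does not either. The miR-1226 precursor lies in an intron of DHX30 (chromosome 3, 47849555 to 47849629, plus strand) and the miR-934 precursor in an intron of VGLL1 (chromosome X, 136550878 to 136550960, plus strand).

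Among the decreases, both arms of miR-455, whose precursor lies in an intron of the collagen gene COL27A1 (chromosome 9, 114209434 to 114209529, plus strand), fell by 1.94 (SE 0.15) for the 5p arm and 1.52 (SE 0.21) for the 3p arm on the log2 scale. Both arms of miR-145 fell, by 1.32 (SE 0.12) for 5p and 1.33 (SE 0.21) for 3p, from a precursor in an intron of CARMN (chromosome 5, 149430646 to 149430733, plus strand). miR-146a-5p, which dampens NF-kappa-B signalling, fell by 1.42 (SE 0.18), miR-212-3p by 1.37 (SE 0.17) and miR-195-3p by 1.68 (SE 0.16). The low-level miR-885-3p went from 13.4 ± 2.61 to 0.488 ± 0.521 CPM, where the knockdown mean lies below the 3-read limit of every library, and miR-3125 went from 11.1 ± 1.43 to 2.14 ± 1.86 CPM. The entries miR-642a-3p and miR-642b-5p both fell by 1.77 (SE 0.16), but they hold the same reads in all 6 libraries and their precursors overlap on opposite strands, so they are 1 measurement that belongs to either. The adjusted p of these decreases was at most 0.0018.

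**Figure D2:**
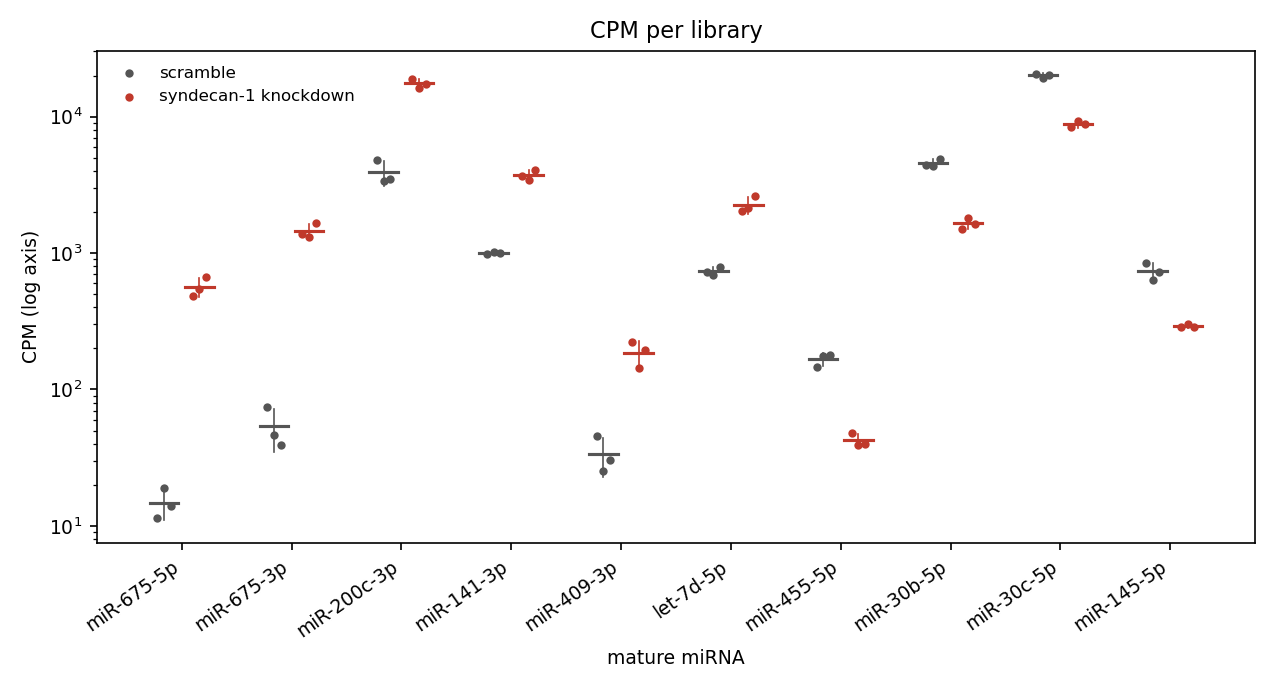
CPM per library (log axis) of 10 miRNAs in 3 scramble libraries (grey) and 3 syndecan-1 knockdown libraries (red); points are libraries, horizontal lines are group means and vertical lines are 1 SD to either side. The groups do not overlap for any of the 10, with miR-675-5p at 14.8 CPM on average in scramble and 565 in knockdown, and miR-30b-5p at 4541 and 1650.

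The most abundant miRNAs changed less. miR-16-5p held 94120 ± 1838 CPM in scramble and 128684 ± 4116 CPM in knockdown (log2 fold change 0.45, SE 0.07), an increase that did not pass after TMM scaling (0.16) or with quantile normalization (0.36). miR-191-5p fell from 96880 ± 7918 to 61558 ± 4844 CPM (log2 fold change -0.65, SE 0.09), and miR-182-5p from 49328 ± 5183 to 36201 ± 868 CPM (-0.44, SE 0.09). The oncogenic miR-21-5p fell by 0.28 (SE 0.09) and miR-23a-3p by 0.23 (SE 0.08), and the value of miR-21-5p was 0.07 with quantile normalization. let-7i-5p (-0.11, SE 0.09), miR-30d-5p (-0.08, SE 0.08) and miR-25-3p (0.08, SE 0.07) did not pass the test. let-7i-5p passed as lower after TMM scaling (-0.40), in edgeR (-0.27) and in DESeq2 (-0.29), and as higher with quantile normalization (0.17), and miR-25-3p was -0.21 after TMM scaling. miR-30d-5p passed as lower after TMM scaling (-0.37), in edgeR (-0.24) and in DESeq2 (-0.26).

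All 10 tested rows of the miR-200 family with miR-205 rose, also after TMM scaling, and all 10 passed when adjusted over the list alone. The summed CPM of the list went from 6883 ± 1029 to 26740 ± 1705. From the locus on chromosome 12 (6963699 to 6964191, plus strand), in introns of MIR200CHG, miR-141-3p rose 3.72-fold (log2 fold change 1.89, SE 0.10), miR-141-5p by a log2 fold change of 1.71 (SE 0.19) and miR-200c-5p by 1.85 (SE 0.26). From the locus on chromosome 1 (1167104 to 1169087, plus strand), miR-200a-3p rose by 1.52 (SE 0.10) and miR-200b-3p by 1.47 (SE 0.14), and miR-205-5p, of squamous and basal epithelium, rose by 1.62 (SE 0.24). The camera test called the list at an adjusted p of 0.00019, with a median 1.39 above that of all tested miRNAs. That call was lost with an adjusted p = 0.374 with an estimated correlation, while fry gave an adjusted p of 0.00057.

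Of 14 tested rows of the imprinted 14q32 cluster, a maternally expressed group of miRNAs, 12 rose and none fell, also after TMM scaling, and 13 rose when adjusted over the list alone. Of the 14 rows, 6 averaged below 10 CPM in scramble, 4 of them among the 12 that rose. With a CPM filter of 1, 22 of 33 rows rose, and with no filter 23 of 75, and none fell in either. Besides those above, miR-127-3p (log2 fold change 1.96, SE 0.24) and miR-494-3p (1.72, SE 0.22) rose, whereas miR-376c-3p (0.72, SE 0.31) and miR-431-5p (0.45, SE 0.24) did not pass over all rows. The precursors of miR-323a (chromosome 14, 101025732 to 101025817) and miR-494 (101029634 to 101029714) lie in introns of MEG8 and that of miR-409 (101065300 to 101065378) in an intron of MEG9, all on the plus strand. The summed CPM of the list, members below the filter included, was 293 ± 23.3 in scramble and 1076 ± 238 in knockdown. Camera called the list at an adjusted p of 0.00019, a call lost with an adjusted p = 0.397 with an estimated correlation, and fry gave an adjusted p of 0.0016.

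The miR-371-373 cluster, known from pluripotent cells, had 4 tested rows and all 4 rose over all rows and when adjusted over the list alone, also after TMM scaling. All 4 averaged below 10 CPM in scramble, so they entered the test through their knockdown values. All 4 also rose with a CPM filter of 1. miR-372-3p rose from 3.79 ± 0.808 to 14.6 ± 2.50 CPM, and miR-371a-5p and miR-371b-3p, which hold the same reads, from 6.48 ± 2.70 to 20.3 ± 4.61 CPM. The precursors of miR-371a, miR-372 and miR-373 lie between 53787675 and 53788773 on chromosome 19 (plus strand). The list had an adjusted p of 0.067 in camera, 0.397 with an estimated correlation, and 0.00057 in fry. In camera it was 0.025 with TMM scaling, 0.049 with quantile normalization, 0.039 with no trend, 0.019 with a CPM filter of 1 and 0.132 with 1 row kept of those with the same reads. In the neighbouring 19q13 primate cluster, miR-516a-5p was the 1 tested row and rose 3.19-fold (log2 fold change 1.62, SE 0.31). It also passed when adjusted over the list alone. Both tested rows of the miR-34/449 family, which act downstream of p53 and in ciliated epithelium, rose over all rows and when adjusted over the list alone: miR-34a-5p by a log2 fold change of 1.10 (SE 0.15) and miR-449c-5p by 1.22 (SE 0.32), of which 1 passed with quantile normalization. These last lists had too few rows for a list test, and neither passed in camera with lower filters, with an adjusted p of 0.214 and 0.328 at a CPM of 1 and of 0.374 and 0.130 with no filter.

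The miR-30 family was the list called as lower. Of 9 tested rows 5 fell, none rose and 4 did not pass, with the same counts when adjusted over the list alone, and 8 fell after TMM scaling. miR-30c-5p fell from 20065 ± 758 to 8818 ± 505 CPM (log2 fold change -1.19, SE 0.08), miR-30a-5p from 24579 ± 3013 to 15014 ± 1504 CPM and miR-30a-3p from 6775 ± 522 to 3963 ± 289 CPM. The precursors of miR-30b (chromosome 8, 134800520 to 134800607, minus strand) and miR-30d (134804876 to 134804945) are neighbours. Camera gave an adjusted p of 0.0022, a call lost with an adjusted p = 0.374 with an estimated correlation, and fry gave 0.0015. The estimated correlation of this list was 0.028, against the preset 0.01, so the loss need not come from correlated members.

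The suppressor miRNAs of lung cancer had 16 tested rows, of which 6 fell, 2 rose and 8 did not pass, with the same counts when adjusted over the list alone and with 9 lower and 2 higher after TMM scaling. Besides miR-145, the myomiRs miR-1-3p (log2 fold change -0.74, SE 0.25) and miR-133a-3p (-0.96, SE 0.21) fell, as did both miR-486 entries, which hold the same reads (2870 ± 284 to 1292 ± 112 CPM). Against these, miR-7-5p, a repressor of EGFR, rose from 364 ± 38.5 to 1441 ± 240 CPM and miR-375 rose by 0.73 (SE 0.12). The list had an adjusted p of 0.067 in camera, 0.397 with an estimated correlation, and 0.011 in fry. In camera it passed as lower with a CPM filter of 1 (0.016), with no filter (0.013) and without scramble replicate 3 (0.048), and had 0.178 with 1 row kept of those with the same reads and 0.528 with a CPM filter of 100. The oncogenic miRNAs of lung cancer had 16 tested rows, of which 9 rose, 5 fell and 2 did not pass, with the same counts when adjusted over the list alone and with 5 higher and 5 lower after TMM scaling. miR-31-5p rose 2.69-fold (log2 fold change 1.39, SE 0.18), miR-222-3p 2.06-fold (1.04, SE 0.11) and miR-183-3p by 1.08 (SE 0.23), while miR-21-3p fell by 0.98 (SE 0.15) and miR-155-5p by 0.45 (SE 0.13). Camera gave the oncogenic list an adjusted p of 0.754, or 0.851 with an estimated correlation, and fry gave 0.047.

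The let-7 family, which represses RAS and HMGA2, had 18 tested rows, of which 8 rose, 4 fell and 6 did not pass, with the same counts when adjusted over the list alone and with 7 higher and 6 lower after TMM scaling. let-7d-5p rose from 736 ± 53.3 to 2259 ± 317 CPM, let-7c-5p from 129 ± 6.82 to 349 ± 118 CPM and let-7a-5p from 4616 ± 121 to 8647 ± 1418 CPM. The 4 that fell were 3p arms, among them miR-98-3p, from 20.2 ± 2.46 to 10.4 ± 1.26 CPM. Camera gave an adjusted p of 0.754, 0.017 (as higher) with a CPM filter of 100, or 0.851 with an estimated correlation, and fry gave 0.011. The miR-29 family, which targets collagens and DNA methyltransferases, had 5 tested rows, of which 4 rose, also when adjusted over the list alone, but 1 rose after TMM scaling. miR-29b-3p rose from 449 ± 21.2 to 943 ± 102 CPM, and miR-29c-3p (0.56, SE 0.16), miR-29b-2-5p (0.64, SE 0.25) and miR-29a-3p (0.27, SE 0.10) also rose, with miR-29a-3p at -0.03 after TMM scaling. Camera gave an adjusted p of 0.369, or 0.699 with an estimated correlation, and fry gave 0.011.

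In the miR-17-92 cluster and its paralogs, which drive proliferation, 5 of 16 tested rows rose, 2 fell and 9 did not pass. Adjusted over the list alone, 5 rose and 1 fell, and after TMM scaling 3 rose and 3 fell. miR-20b-5p rose from 11.9 ± 3.10 to 44.2 ± 6.56 CPM and miR-363-3p from 6.00 ± 3.01 to 12.6 ± 2.01 CPM, both from the paralog locus on chromosome X, and miR-17-3p rose by 0.93 (SE 0.24), while miR-19b-3p fell from 3973 ± 221 to 1928 ± 376 CPM. miR-17-5p, the more abundant arm of miR-17, did not pass (0.12, SE 0.14). In the miR-15/16 family 3 of 12 tested rows rose, 3 fell and 6 did not pass. Adjusted over the list alone, 2 rose and 2 fell, and after TMM scaling none rose and 5 fell. miR-15b-5p (0.51, SE 0.15) and miR-16-5p rose, and miR-195-5p (-0.87, SE 0.11) and miR-195-3p fell. Camera gave adjusted p values of 0.754 for the miR-17-92 list and 0.369 for the miR-15/16 list, 0.851 and 0.742 with an estimated correlation, and fry gave 0.063 and 0.017.

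**Figure D3:**
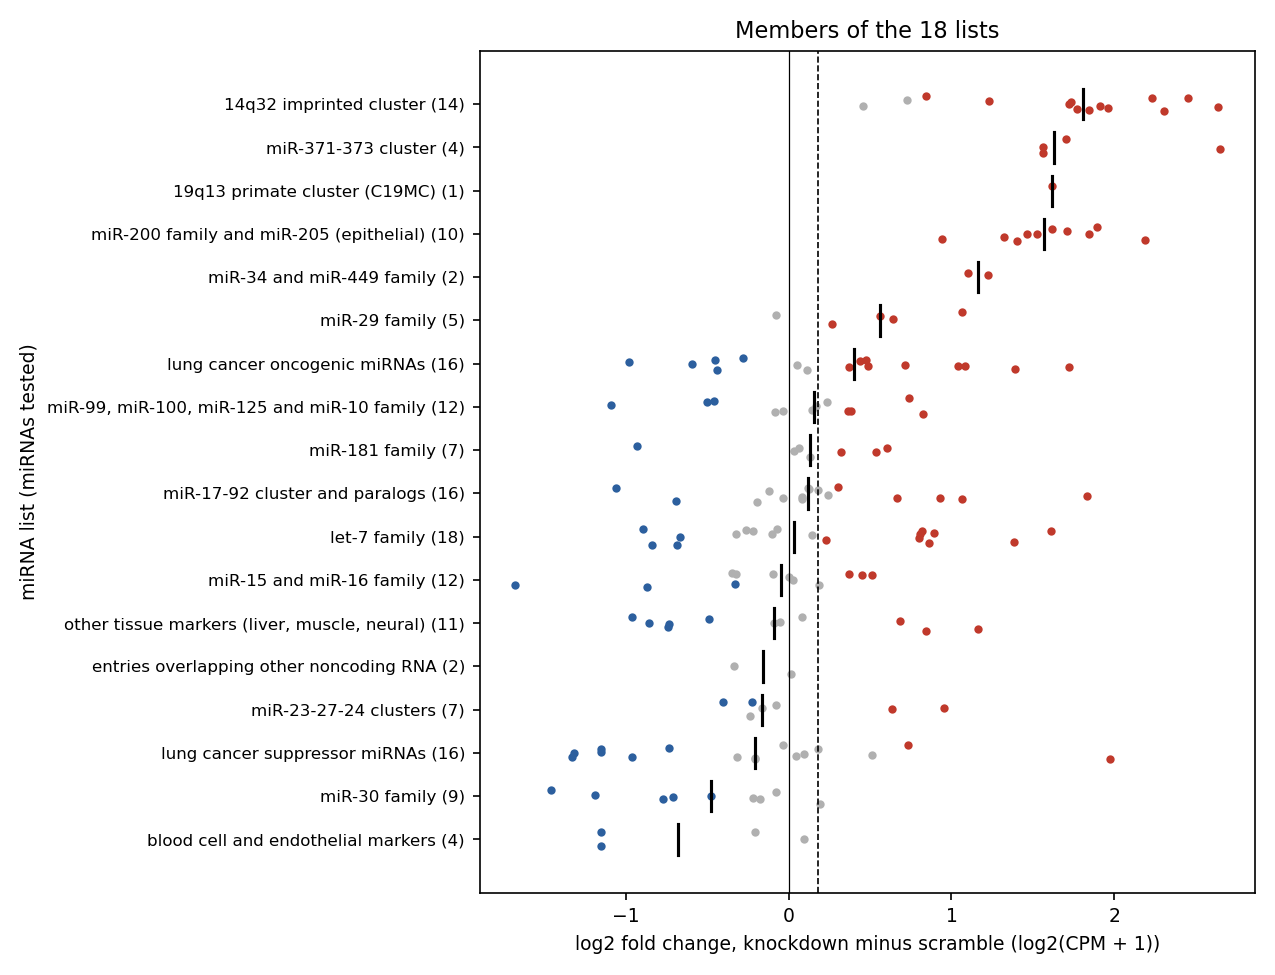
Log2 fold changes (knockdown minus scramble, log2(CPM + 1)) of the tested members of the 18 lists, with the number tested in parentheses; red points rose, blue points fell and grey points did not pass at an adjusted p under 0.05, short black bars are list medians and the dashed line is the median of all 428 miRNAs (0.18). All 10 rows of the miR-200 family with miR-205 and 12 of 14 rows of the 14q32 cluster rose, also after TMM scaling, whereas 5 of 9 rows of the miR-30 family fell (8 after TMM scaling).

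Further families went both ways. In the miR-181 family 3 of 7 tested rows rose (miR-181a-5p by 0.61, miR-181b-5p by 0.54 and miR-181a-2-3p by 0.32), 1 fell (miR-181c-3p, -0.93) and 3 did not pass, with the same counts when adjusted over the list alone and 2 and 1 after TMM scaling. In the miR-99/100/125/10 family 4 of 12 tested rows rose, 3 fell and 5 did not pass, with the same counts when adjusted over the list alone and 2 and 4 after TMM scaling. miR-125a-5p rose from 10822 ± 1231 to 18173 ± 3006 CPM and miR-99a-5p by 0.82 (SE 0.20), and miR-10a-3p (-1.09, SE 0.10) and miR-10a-5p (-0.50, SE 0.11) fell. In the miR-23-27-24 clusters 2 of 7 tested rows rose (miR-27a-5p by 0.95 and miR-23b-3p by 0.64), 2 fell (miR-27b-3p, -0.41, and miR-23a-3p, -0.23) and 3 did not pass, with the same counts when adjusted over the list alone and 2 and 5 after TMM scaling. miR-27a-3p, the more abundant arm of miR-27a, did not pass (-0.08, SE 0.09). The adjusted p in camera was 0.754, 0.754 and 0.557 for these lists, 0.851, 0.851 and 0.815 with an estimated correlation, and 0.072, 0.805 and 0.743 in fry. The median and the mean of the miR-99/100/125/10 list were positive (0.16 and 0.06) where camera ranked it lower, and the miR-23-27-24 list had a median of -0.16 and a mean of 0.07.

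The 2 lists of markers of other cell types did not pass in camera, except that the blood list passed without scramble replicate 3 (0.048), and it had 0.331 with 1 row kept of those with the same reads. Of 4 tested rows of the blood cell and endothelial list, the 2 miR-486 entries fell (log2 fold change -1.15, SE 0.11, the same reads) and the 2 arms of miR-126 did not pass, with the same counts when adjusted over the list alone and 3 lower after TMM scaling. The red cell miRNA miR-451a was at 0.243 ± 0.421 CPM in scramble and 1.29 ± 1.16 CPM in knockdown, below the filter. Camera gave this list an adjusted p of 0.067, or 0.692 with an estimated correlation, and fry gave 0.013. Of 11 tested markers of liver, muscle and neural tissue, 3 rose (miR-9-5p by 1.16, and the 2 arms of miR-122, miR-122-3p by 0.85 and miR-122-5p by 0.69), 5 fell, among them miR-338-3p (-0.86) and miR-133a-3p, and 3 did not pass. The other arm of miR-9, miR-9-3p, was among those that fell (-0.49, SE 0.16). The counts were the same when adjusted over the list alone and were 1 and 6 after TMM scaling, and miR-338-3p and both miR-122 arms share all their reads with an entry on the opposite strand. Camera gave an adjusted p of 0.369, or 0.699 with an estimated correlation, and fry gave 0.208. Of the entries that overlap other noncoding RNA, 2 were tested and neither passed, over all rows or adjusted over the list alone (miR-1246 0.02, SE 0.14, and miR-6087 -0.33, SE 0.34), and the list was too small for a list test (camera adjusted p of 0.806 with a CPM filter of 1 and 0.800 with no filter).

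The make-up of the libraries differed between the groups. The 10 most abundant miRNAs held 49.9% ± 0.617 of the CPM in scramble and 48.0% ± 0.269 in knockdown (SD, n = 3 per group; exact permutation p = 0.1, two-sided, the smallest this design allows). At a CPM of at least 1, 787 ± 19.6 miRNAs were detected in scramble and 892 ± 39.6 in knockdown (exact permutation p = 0.1, two-sided). Entries that overlap other noncoding RNA, mostly miR-1246, held 0.0129% ± 0.00119 and 0.0140% ± 0.000657 of the CPM (exact permutation p = 0.3, two-sided), which is small in every library. On log2 values, Pearson correlations between libraries, taken across miRNAs, lay between 0.993 and 0.997 within a group and between 0.954 and 0.964 across groups, and the first principal component, with 84.9% of the variance, separated the groups.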

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

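The main settings and all alternatives but 1 were fixed before the data were examined; keeping 1 row of each pair with the same reads was added afterwards. The counts of higher (171) and lower (93) miRNAs stayed within 1.5 times under the other settings, except that 79 were higher with a CPM filter of 100 (fewer rows tested), 111 higher and 154 lower with TMM scaling, and 113 higher with quantile normalization. On recovered reads edgeR found 136 higher and 128 lower and kept 229 of the 264 calls, and DESeq2 found 127 and 134. Leaving out 1 library gave 134 to 160 higher and 74 to 92 lower. Of the lists, 3 passed in camera, 5 with a CPM filter of 1 and 5 with no filter (the suppressor and miR-371-373 lists added), 10 in fry, and 0 in camera with an estimated correlation (2 at an unadjusted p under 0.05). Leaving out 1 library gave 3 to 6 lists, with 6 without scramble replicate 3, where the suppressor, miR-371-373 and blood lists were added, and miR-371-373 was added without scramble replicate 2. The miR-371-373 list also passed with TMM scaling, quantile normalization and no trend, but not with 1 row of each pair kept, and the let-7 list passed as higher with a CPM filter of 100. With any knockdown library left out, or with a CPM filter of 100, the miR-371-373 list had too few rows to be tested. It passed in 7 of the 14 settings in which it could be tested. The cause of these differences was not tested. Estimated correlations were 0.028 for the miR-30 list, 0.193 for the miR-200 list and 0.370 for the 14q32 list. The lost calls, above all that of the miR-30 list, therefore do not show that correlated members account for them. With the preset correlation, the miR-200 and miR-30 lists kept their camera call in 18 of 18 settings and the 14q32 list in the 17 in which it could be tested, as a CPM filter of 100 left too few of its rows. The difference in miRNAs detected was 104 at a CPM of 1 (81.7 to 118 without 1 library) and 36.7 at a CPM of 10, where fewer rows count. The share of CPM in the 10 most abundant miRNAs differed by -1.91 percentage points (-2.17 to -1.57) and the share of CPM in entries overlapping other noncoding RNA by 0.00114 (0.000653 to 0.0018). With the replicate block, 172 miRNAs were higher, 97 lower and 3 lists passed. Same-numbered libraries correlated at 0.049, 0.047 and 0.027 in their deviations, under the 0.1 set for pairing, though each correlated best with its own number. Among the named miRNAs, settings gave 1398 values on the same side, 54 no longer past the threshold, 6 newly past it and 7 with the sign reversed. The reversed values were miR-25-3p (-0.21 with TMM, -0.0867 with quantile normalization, -0.0757 with edgeR, -0.10 with DESeq2), miR-29a-3p (-0.0291 with TMM), miR-21-5p (0.0671 with quantile normalization) and let-7i-5p (0.17 with quantile normalization), whose cause was not tested. Depth limits values near the 3-read limit, such as miR-885-3p and miR-3125.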

Other observations

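All tests in this part but the thinning of the libraries were chosen after the results were seen. Tested miRNAs were grouped into 25 genomic clusters (precursors at 1 locus each, within 10000 bases on 1 strand, with at least 3 tested rows), and camera called 4 of them. The cluster outside the fixed lists was that of miR-191 and miR-425 on chromosome 3 (49020148 to 49020709, minus strand), where all 4 tested rows fell, also after TMM scaling and with quantile normalization, with a median log2 fold change of -0.77 and an adjusted p of 0.013. The others were the 14q32 segment from miR-379 to miR-409 (9 of 10 rows rose, adjusted p of 0.0024) and both miR-200 loci, miR-200c with miR-141 (4 of 4 rose, adjusted p of 0.018) and miR-200b, miR-200a and miR-429 (5 of 5 rose, adjusted p of 0.021). All 4 calls were lost with an adjusted p = 0.523 with an estimated correlation, where no cluster had an unadjusted p under 0.05 (lowest 0.061). Both tested rows of miR-221 and the 1 of miR-222 on chromosome X rose (median 0.72, with 2 of the 3 past the test after TMM scaling), although their cluster did not pass in camera (adjusted p of 0.161).

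A hypothesis is that part of the change was set by the supply of precursors, since both arms of a precursor would then change together. Across the 98 precursors with both arms tested and no shared rows, the log2 fold changes of the 5p and 3p arms correlated with Pearson's r of 0.657 and Spearman's rho of 0.388 (permutation p = 1e-05, the smallest that 100000 permutations can give, and 7e-05). Without the 2 precursors farthest from the median, miR-675 and miR-455, r was 0.453. Precursors are not independent replicates. Copies at several loci were grouped under a shared name, and the most abundant row of each arm was taken. The rows of such a name can come from different loci, as for miR-7-5p with miR-7-1-3p, so they need not share a precursor. Where both arms passed the test, they moved the same way in 29 of 37 precursors, and the 8 exceptions were let-7a, let-7f, miR-98, miR-9, miR-92b, miR-296, miR-361 and miR-378a. Whether cells or packaging set the supply was not measured.

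Of 9 tested let-7 5p rows 7 rose, none fell and 2 did not pass (let-7g-5p and let-7i-5p, of which let-7i-5p passed as lower after TMM scaling, in edgeR and in DESeq2 and as higher with quantile normalization), and of 9 tested 3p rows 4 fell, let-7d-3p rose (0.81) and 4 did not pass. Within each of 7 members with both arms tested the 3p to 5p ratio was lower in knockdown, with no overlap between groups, by a median of -0.94 on the log2 scale, against -0.03 in 91 other precursors (quartiles -0.50 and 0.34, with larger drops such as -2.29 for miR-7 and -1.65 for miR-9, which have several precursor loci). For let-7a and let-7f the more abundant 3p row was used. Their other rows, let-7a-3p (-0.32) and let-7f-2-3p (-0.26), fell less and did not pass. The 3p row of let-7g lay under the filter and showed no such drop. It held 6.44 ± 1.16 CPM in scramble and 8.09 ± 1.34 CPM in knockdown, while let-7g-5p changed by 0.14. The drop in the 7 members argues against scaling, since 1 factor per library leaves a ratio within a library alone. For the 5 members with 1 precursor locus (median -0.80), precursor supply alone is argued against only if their 5p rows hold no paralog reads. Whether they do is not known, as the treatment of reads with several matches is not given. For let-7a and let-7f (median -1.52), whose 5p rows sum several loci, precursor supply cannot be told apart. Reads moving between let-7 paralogs, which differ by few bases, cannot be told apart either, because let-7i-5p and let-7b-5p hold 76.5% of the summed CPM of the 5p rows, which changed by 0.0174 more than the median of all tested miRNAs (79710 ± 3916 to 91472 ± 7423 CPM), and a change in which arm is kept in exosomes remains a hypothesis beside these.

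More miRNAs were higher (171) than lower (93). Per-million scaling with a changed make-up of the library cannot be told apart from a true excess. After TMM scaling 41.9% of the calls were higher, against 64.8%. The share was 51.5% in edgeR, 48.7% in DESeq2, 47.1% with quantile normalization and 61.7% when rescaled without the 10 most abundant rows. TMM applies 1 factor per library, so it must lower all log2 fold changes nearly alike (by 0.175 to 0.295), and that likeness decides nothing. The values hold no outside reference for the right scaling. Depth is argued against, because with all libraries thinned to the shallowest a median of 63.7% of calls were higher over 5 draws (63.5 to 65.8). At that equal depth more miRNAs still had a read in knockdown (1150 ± 27.4) than in scramble (1034 ± 11.1, n = 3 per group), so a wider range of miRNAs in knockdown exosomes stays open. The real grouping gave 264 calls in limma and the highest of the other splits gave 0 (at most 4 at an unadjusted p under 0.05, against 281), so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each other split mixes both groups, so their difference enters the spread and leaves little room for calls. The splits therefore decide nothing here.

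Among rows with at least 50 reads, 22 pairs held the same reads in all 6 libraries, such as miR-423-5p with miR-3184-3p (156200 reads). In all 22 pairs the precursors overlap on opposite strands, and in 0 pairs do they lie apart. This argues against reads shared between paralogs at separate loci only as the source of these 22 pairs. Paralogs that share part of their reads need not hold equal reads, so such sharing stays open. Counting that ignored strand is a candidate explanation: of overlapping pairs with at least 50 reads in either compared row, all 10 at 1 locus each held the same reads, whereas 4 of 5 with a member at several loci did not in the rows compared, such as miR-3074-5p (198981 reads) with miR-24-3p (351025) and miR-7-5p (14393) with miR-3529-3p (28). Of these 4, 1 set miR-219a-5p (252 reads) against miR-219b-5p (215). Its other row, miR-219a-2-3p, held the same 215 reads as miR-219b-5p and is among the 22 pairs. Overlapping copies that share a name were left out of this comparison, although they too lie at several loci. Among the 22 pairs are the 5p and 3p rows of such copies, namely miR-486 (31486 reads), miR-3158, miR-3130, miR-3688, miR-3913 and miR-5583. The contrast between 1 locus and several loci therefore covers differently named rows only. With fewer reads, 3 pairs at 1 locus each differed (miR-3155a 9 and miR-3155b 5, miR-451a 11 and miR-451b 0, miR-5683 24 and miR-7853-5p 0). The second rows held 2.52% to 2.72% of the CPM of a library, and with 1 row of each pair kept, 251 of the 264 calls remained and 13 of the calls were second rows, and no biological explanation was tested.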
